A study of Drosophila melanogaster with 3 samples.

How the data were processed

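ChIP-seq was measured in whole Drosophila melanogaster embryos aged 0 to 24 h that carried an eGFP-tagged copy of CG3726, with an antibody against GFP. The labels number the samples as biological replicates 1, 2 and 3 of 1 group, and chromatin was sonicated to fragments of 200 to 800 bp, per the labels. A control experiment is named in the labels as a possible control and was not used here.

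The authors deposited peak lists on dm6, per the labels. The aligner, the peak caller and their versions are not given in the sources used here. Each replicate has a ranked list of candidate peaks and a list thresholded on the irreproducible discovery rate (IDR), a measure of how far peak ranks repeat between sets of reads. Lists of the whole series, which the deposited notes derive from the alignments of all 3 samples, come in the same kinds. The lists of single replicates were thus called per sample, and the series-wide lists on pooled samples. How much each replicate contributed to a series-wide list, the conservative list included, cannot be told from the peak lists. Which replicates were set against each other for the other series-wide lists is not given in the sources used here, so what the largest list rests on is not known. The signal value of each peak is the authors' peak caller's own value, with no stated scale, and was used only to describe and rank peaks within a list. The score of each peak in the deposited lists is the IDR rescaled to at most 1000. The lowest score in the deposited thresholded lists is 830, which is an IDR of 0.01. The ranked lists also hold the −log10 of the IDR as the authors deposited it. The p-value column of the lists holds no values, so ties in signal were broken by position. Read depth is not given in the peak lists, so the number of peaks is the only depth-related value of each replicate. Intervals cover counting error only.

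The main list was the series-wide conservative IDR-thresholded list. Peaks on X, 2L, 2R, 3L, 3R and 4 (the 6 arms) were analysed, and peaks on other sequences were only counted. Gene models came from Ensembl release 115 on the BDGP6 assembly, whose arms have the coordinates of dm6, and sequence came from the RefSeq copy of that assembly. No candidate peak of a single replicate extended past the end of an arm. The 6 arms held 13945 protein-coding genes, 290 tRNA genes and 5809 annotated transposable elements.

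A conservative peak counted as shared with a replicate when it overlapped a thresholded peak of that replicate by at least 1 bp. The planned comparison of this share with random placements is not reported, because the conservative list was made from reads of the same replicates, which fixes its outcome. Signal values of conservative peaks were taken from the strongest overlapping peak in each replicate's ranked list, and Spearman's rho was computed across peaks, which are not independent replicates. A summit within 500 bp of the transcription start site (TSS) of a protein-coding transcript was a promoter summit, and the promoter share was compared with 1000 random placements, two-sided. Peaks per arm were tested with exact binomial tests, adjusted by Benjamini-Hochberg over the 6 arms. A gene had a peak when a summit lay within 1000 bp of any of its TSSs. The 27 gene lists were tested with Fisher's exact test, two-sided, against all other protein-coding genes of the arms, adjusted over the lists. 9 listed symbols were matched to their current names through a synonym table, and every listed gene was then found. Consensus motifs (28) and all 2080 words of 6 bases, with reverse complements merged, were counted in 200 bp windows centred on the summits and compared by Fisher's exact test with 10 control windows per peak. The summit of each peak was placed by the summit offset in the deposited lists. Controls were matched on the distance class of the nearest TSS and on GC content in bins of 2.5 percentage points, lay over 1000 bp from any thresholded summit of the lists analysed, and had a mean GC content of 37.3%, as did the peak windows. Shares carry Wilson 95% confidence intervals, and for a share of 0 the limit is 3 counts of the total. Odds ratios had 0.5 added to each count.

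The genes named were set by rule. They were the first 25 different genes in order of signal with the nearest TSS within 1000 bp of a summit, up to 4 members of each list with the highest signal, CG3726, the 5 strongest peaks without a protein-coding TSS within 1000 bp, and up to 10 words in each direction by odds ratio. The design, gene lists, motifs, naming rule and a first set of alternatives were fixed before the data were examined. Alternatives included other windows, overlap rules, peak lists, controls and gene rules, and the omission of each replicate where single-replicate lists were compared. Later alternatives, chosen after seeing the data, were the highest score only, an IDR of up to 0.05, merged peaks, tRNA-adjacent peaks left out and repeat-masked windows left out.

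The tests were tested on simulated data before the final run; the gene lists and words had been looked at once in the peak lists by then. With 1 of 27 gene lists enriched on purpose, 1 list was called, the enriched one. With a word planted in 10% of 1837 windows, 2 motifs were called, the planted one among them. All 4 of the 6-base words inside the planted word were called, with 6 other 6-base words. Without a planted word, 0 of 2080 words and 1 of 28 motifs (DRE) were called, and because DRE was the motif planted at first, the CTCF consensus was planted in its place. Of 100 sets of uniformly placed summits, 3 had a promoter share with a permutation p under 0.05. Software was Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9.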

Results

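The binding of an eGFP-tagged CG3726 protein to chromatin was mapped by ChIP-seq with an antibody against GFP in whole embryos collected over 0 to 24 h, in 3 biological replicates of 1 group. CG3726 was the tagged gene, and the fusion protein was the target of the immunoprecipitation. With no second group, the comparisons that follow are between replicates, between peaks and the genome, and between gene groups.

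The IDR-thresholded lists held 1189 peaks in replicate 1, 1351 in replicate 2 and 903 in replicate 3 (1148 ± 227, mean ± SD, n = 3). On the 6 arms they held 1147, 1270 and 903 peaks. The series-wide conservative list held 1934 peaks, of which 1849 lay on the 6 arms, and 1645 of the 1934 peaks had the same width of 336 bp. The largest series-wide thresholded list held 3204 peaks. Signal values in the conservative list ran from 2.31 to 1726 with a median of 140.3, on the scale of the authors' peak caller.

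Of the 1849 conservative peaks, 522 (28.2%, Wilson 95% interval 26.2 to 30.3%) overlapped a thresholded peak in all 3 replicates. Replicate 1 covered 57.9%, replicate 2 63.3% and replicate 3 34.6% of the conservative peaks, and 476 peaks (25.7%) were covered by no replicate list. How much each replicate contributed to the conservative list is not known, which limits what the lower share of replicate 3 shows. Without replicate 3, the share covered by both other replicates was 48.7%, and in the largest list the share covered by all 3 was 16.4%. When each peak and its match had to overlap by at least 50% of the length of each, it was 20.6%. Of the peaks of replicate 1, 76.1% overlapped a peak of replicate 2 and 48.6% a peak of replicate 3. For replicate 2 the shares were 69.0% in replicate 1 and 45.0% in replicate 3, and for replicate 3, whose list is the shortest, 62.2% in replicate 1 and 63.9% in replicate 2. When the candidate lists were searched, 98.8%, 98.2% and 95.7% of conservative peaks were matched in replicates 1, 2 and 3. Those lists held 121639, 122888 and 124680 peaks with summed widths of 35972214, 34373459 and 34894086 bp. Part of the matches would thus arise at random positions too, and that share was not computed. The signal of matched peaks had a Spearman's rho across peaks of 0.768 between replicates 1 and 2, 0.657 between 1 and 3 and 0.67 between 2 and 3 (mean 0.698 ± 0.0606, SD over 3 pairs). The conservative peaks were kept by an IDR threshold, which favours ranks that repeat, on reads of the same replicates. These values thus describe selected peaks, which are not independent replicates, and no p is given.

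**Figure D1:**
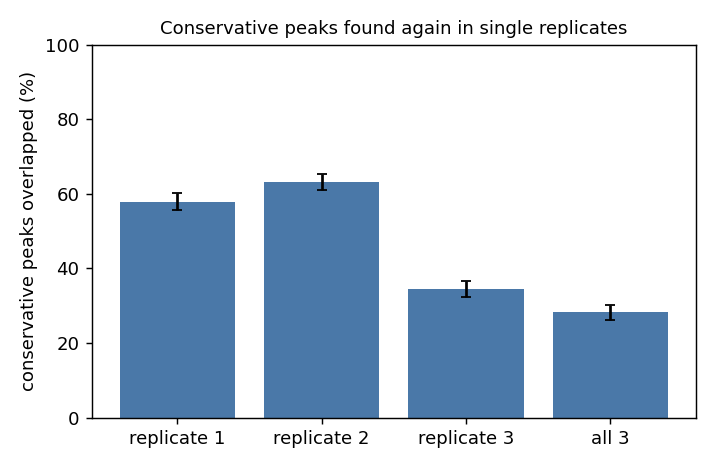
Share of the 1849 conservative peaks (y axis, %) overlapped by a thresholded peak of each replicate and of all 3 replicates (x axis); error bars are Wilson 95% intervals. Replicate 3 covered 34.6%, less than replicates 1 and 2 at 57.9% and 63.3%.

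The tagged gene itself carried one of the strongest peaks. CG3726 (FBgn0029824) lies at X, 5917097 to 5941852, on the plus strand. The peak at X, 5918804 to 5919024, in its intron, had its summit 1761 bp from the nearest CG3726 TSS. It ranked 5 of 1849 conservative peaks by signal, and it ranked 4 of 1147 in replicate 1, 7 of 1270 in replicate 2 and 8 of 903 in replicate 3. The largest list held another intronic peak inside CG3726 at 5932583 to 5932918 (signal 90.4) and a peak with its summit 935 bp upstream of the TSS at 5915994 to 5916329 (signal 71.2), against 1276 for the first. The nearest TSS belonged to CG12728 for the former of these weaker peaks and to Shmt for the latter. No control was analysed here, and how many copies of this locus the embryos carried cannot be told from peak lists. The strong peak alone thus does not show that the protein acts on its own gene.

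**Figure D2:**
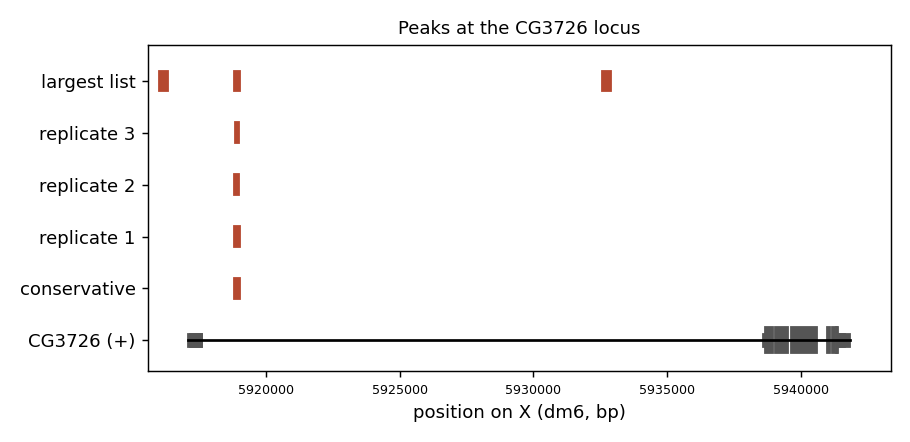
Map of CG3726 on X (x axis, dm6 position in bp; tall boxes are coding sequence, low boxes untranslated regions, the line is the gene) with thresholded peaks of each list as red boxes (y axis). The intronic peak at 5918804 was found in the conservative list and in all 3 replicates.

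The 25 genes with the strongest peaks within 1000 bp of a TSS each had a peak that overlapped a thresholded peak in all 3 replicates. These peaks were picked by signal in a list made from reads of the same replicates, so the overlap follows in part from the choice. The median distance from summit to TSS was 122 bp, and 19 of the 25 summits lay upstream of the TSS of the named gene. The highest signal (1726) was at Ugalt, a UDP-galactose transporter gene, at X, 2703755 to 2704023, with the summit 45 bp upstream of the TSS and eIF2Bbeta, a translation initiation factor gene, within 1000 bp. CG14100 on 3L (19590469 to 19590744) had signal 1629, with the summit 90 bp upstream of its TSS. The peak at mRpL41, a mitochondrial ribosomal protein gene on 2R (15217622 to 15217884, signal 1387), lay 131 bp upstream of its TSS. ph-p, a Polycomb group gene on X (2137230 to 2137484, signal 1317), had its peak in an intron, 497 bp from the nearest TSS. Tcs5 on 3L had signal 1251, CG7601 on 3R 1181, and Art3, a protein arginine methyltransferase gene on 3R, 1143. Chro, which encodes a chromodomain protein of interbands and insulators, had signal 1114 on 3L in the 5′ UTR, 90 bp downstream of its TSS. px and CenG1A followed with 1091 and 1089, PNPase, a mitochondrial RNA-processing enzyme gene, with 1073, CG5611 with 1037 and HmgZ, a high mobility group gene, with 1014. Signal was 923 at CG18549, 896 at Adf1, a transcription factor gene, 894 at eIF6, 876 at tank, 872 at Fkbp14 and 859 at mRpL23. The remaining genes were Shc (844), CG8320 (834), CG13390 (815), GstE13 (800.1), Rtnl1 (787) and Sox14 (770). 16 of the 25 had another gene with a TSS within 1000 bp of the summit, so these peaks are not assigned to a single gene. The 5 strongest peaks with no protein-coding TSS within 1000 bp were in introns of CG3726, CG11050 (2L, 6612597 to 6612857), CG32772 (X, 4910256 to 4910487) and Tlk (X, 3742105 to 3742339), and between genes on 2R (13035231 to 13035440), 11912 bp from the TSS of CG13323.

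Summits were concentrated at promoters. Of 1849 conservative summits, 791 (42.8%, Wilson 95% interval 40.5 to 45.0%) lay within 500 bp of a protein-coding TSS, against 11.5% on average and at most 13.8% in random placements, 3.71-fold (permutation test, two-sided, p = 0.002, the smallest the placements can give). The lists of replicates 1, 2 and 3 gave 47.6%, 47.9% and 48.8% (48.1 ± 0.649%, SD, n = 3). 659 of the 791 promoter summits (83.3%) lay upstream of the nearest TSS, at a median of -118 bp. Of all 1849 summits, 34.8% were in introns outside promoters against 39.9% at random, and 17.0% were intergenic outside promoters against 27.8%. Coding exons outside promoters held 2.54% against 13.9%, and 3′ UTRs 0.487% against 4.53%. These shares are of all summits, so the larger promoter share lowers each of the others. A lower share is thus not by itself a depletion among summits outside promoters, for which shares were not computed. Annotated transposable elements held 6 summits (0.324%) against 5.74% at random. How reads in repeats were treated is not given in the sources used here. 4 summits (0.216%) lay within 500 bp of a tRNA gene, against 3.02 on average in 200 random placements (permutation p = 0.716).

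Stronger peaks were more often at promoters. When the list was divided by signal into 4 groups of near-equal size, 56.1% of 462 summits in the strongest group lay at promoters. The share was 45.2%, 37.7% and 32.2% in the groups that followed. The strongest group exceeded the weakest by 23.9 percentage points (odds ratio 2.68, 95% interval 2.05 to 3.51, Fisher's exact p = 2.55e-13). The comparison was made within the conservative list only.

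**Figure D3:**
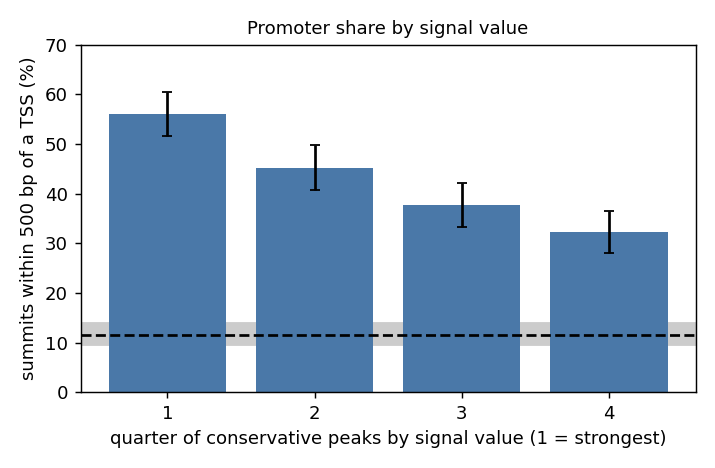
Share of summits within 500 bp of a protein-coding TSS (y axis, %) in each of 4 groups of conservative peaks by signal (x axis), with Wilson 95% intervals; the dashed line and grey band are the mean and range of 1000 random placements of all peaks. The share was 56.1% in the strongest group and 32.2% in the weakest.

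The peaks were spread over the large arms close to their length, with chromosome 4 as the exception. The conservative list held 0 peaks on 4, where length gives 18.6, which allows a share of up to 0.162% by the limit of 3 counts, against 1.01% by length (exact binomial adjusted p = 9.04e-08). X held 19.5% of peaks against 17.6% by length (exact binomial adjusted p = 0.0902), and 2L, 2R, 3L and 3R also did not pass. Expected by the number of TSSs, X was higher (17.0% expected) and 2R lower (17.7% against 20.5%, exact binomial adjusted p = 0.00967 for both). With the highest score only, X was higher by length too (21.5%, exact binomial adjusted p = 0.000679). It was lower in the largest list (15.8%, exact binomial adjusted p = 0.0266), where 2L (19.1%) and 3L (22.7%) were higher. With an IDR of up to 0.05, X was also lower (15.6%), and 2L (19.8%) and 3R (26.2%) were higher. Replicates 1 and 2 held 0 peaks on 4 and replicate 3 held 3 (0.332%, exact binomial adjusted p = 0.102). Among the 522 peaks shared by all replicates, 0 on 4 did not pass (exact binomial adjusted p = 0.076).

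1253 of 13945 protein-coding genes (8.99%) had a conservative summit within 1000 bp of a TSS, and 3 of the 27 gene lists passed the test. Cytosolic ribosomal protein genes, which encode the translation machinery, had peaks in 29 of 93 members (31.2%, against 8.84% of other genes, odds ratio 4.72, 95% interval 3.04 to 7.32, Fisher's exact adjusted p = 3.18e-08), with 20, 26 and 24 members in replicates 1, 2 and 3. The members with the highest signal were RpS27 (384), RpL7 (304), RpL32 (285) and RpL34b (257). Each had another gene with a TSS within 1000 bp of the summit, namely Nup37, Ripalpha, CG7943 and CG8132 in that order. With only the gene of the nearest TSS counted, 24 members had a peak (odds ratio 5.38, Fisher's exact adjusted p = 4.69e-08). Chemoreceptor genes had peaks in 2 of 179 members (odds ratio 0.141, Fisher's exact adjusted p = 0.000215), Or88a (194) and Ir48c (122), and cuticle protein genes in 0 of 118 (adjusted p = 0.00025). The Ir48c peak lay 954 bp from its TSS, in the 5′ UTR of ths, and overlapped a thresholded peak in 0 replicates. The cuticle protein call was lost with the 522 peaks shared by all replicates, which also reached 0 of the 118 members (odds ratio 0.126, Fisher's exact adjusted p = 0.234). When genes were matched on TSS number and length, the 3 lists passed too, with 9.90 ribosomal protein genes expected by permutation against the 29 observed (permutation adjusted p = 0.0027). Genes were not matched on expression. Both tests count genes as independent, so their p-values may be too small where members of a list lie side by side, as a region without peaks then counts more than once.

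Of the other lists none passed after adjustment, and 6 of 27 passed without adjustment, the 3 above among them. Insulator protein genes had peaks in 4 of 12 members (odds ratio 5.37, Fisher's exact adjusted p = 0.0997), Chro (1114), Cp190 (423), pita (96.2) and M1BP (85.1), with 1.26 members expected among genes matched on TSS number and length (permutation adjusted p = 0.302). Polycomb group genes had peaks in 5 of 18 (odds ratio 4.14, Fisher's exact adjusted p = 0.0997), including ph-p (1317), ph-d (268), E(z) (255) and Su(z)12 (147). They passed with the highest score only (odds ratio 5.28, Fisher's exact adjusted p = 0.0498), but not with summits within 500 bp (2.75, Fisher's exact adjusted p = 0.586) or against matched genes (1.95 expected, permutation adjusted p = 0.315). Heat shock genes had peaks in 4 of 16 (Fisher's exact adjusted p = 0.221), Hsp27 (576), Hsp83 (282), Hsc70-4 (166) and Hsp26 (107). Mitochondrial ribosomal protein genes had peaks in 10 of 73 (13.7%, Fisher's exact adjusted p = 0.569, 0.0311 with peaks shared by all replicates, and permutation adjusted p = 0.0661 against matched genes), led by mRpL41, mRpS10, mRpS23 and mRpL23. Each of these had another gene with a TSS within 1000 bp of the summit, namely CG8079, Art3, CenG1A and CG9004 in that order. Notch pathway genes had peaks in 3 of 16 members, numb (368), E(spl)mdelta-HLH (159) and E(spl)m3-HLH (153), and cell cycle genes in 3 of 26, Dp (313), Mcm2 (149) and CycE (136). Oxidative phosphorylation genes had peaks in 4 of 80, ND-ASHI (336), ND-MWFE (251), ATPsynCF6 (177) and ATPsynE (66.7), and proteasome genes in 2 of 48, Rpn3 and Prosbeta6. Germline genes had peaks at bgcn (219) and nanos (71.3), 2 of 14, and mesoderm and muscle genes at tin (270.1) and sls (174), 2 of 22. Lists with 1 member each were segment polarity genes (Wnt6, 90.9), dorsoventral genes (brk, 144), neuronal differentiation genes (elav, 424), endoderm genes (bowl, 433), trachea and epidermis genes (trh, 131), BTB-domain genes (ken, 76.6), ecdysone pathway genes (usp, 94.9) and trithorax group genes (brm, 619). The named peaks at M1BP, Hsp26, ATPsynE, Prosbeta6, nanos, ken and usp overlapped a thresholded peak in 0 replicates. The other peaks named here did so in at least 1 replicate. Several peaks lay inside another gene, such as nanos in CG11779, ATPsynCF6 in Sec13, ND-ASHI in Fum1 and brk in CG1677. Peaks near more than 1 gene are thus not assigned to a single gene. Hox, gap, pair-rule, proneural, hemocyte and fat body, and yolk and chorion genes had 0 members with a peak, in lists of 8, 12, 10, 22, 15 and 13 members, sizes at which a count of 0 did not pass (Fisher's exact adjusted p from 0.766 to 1). When a summit anywhere in the gene body also counted, dorsoventral (odds ratio 3.73), BTB-domain (4.80) and ecdysone pathway genes (6.73) passed in the direction of excess, as did trachea and epidermis genes near TSSs with an IDR of up to 0.05 (5.15). The gene-body rule gives longer genes more room for a summit and was not matched on length, so it does not separate this excess from gene length. By the TSS rule, matched genes gave 2.44 dorsoventral, 3.39 BTB-domain and 3.31 ecdysone pathway members expected, against 1 observed in each.

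**Figure D4:**
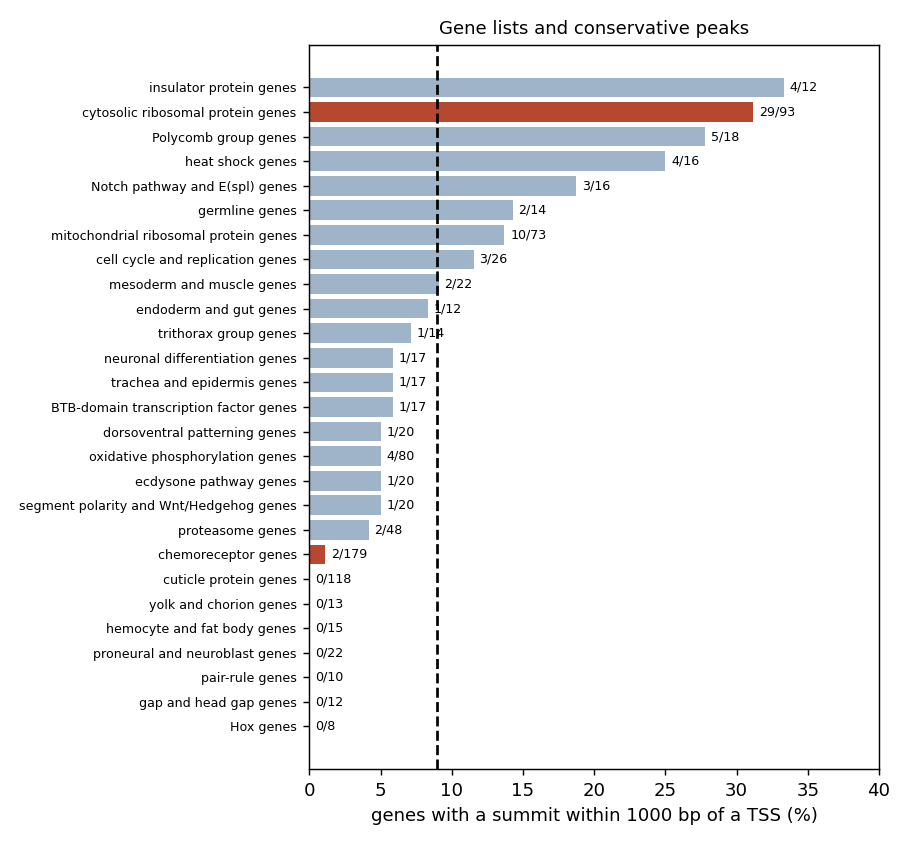
Share of the genes of each list (y axis) with a conservative summit within 1000 bp of a TSS (x axis, %), with members with a peak and all members beside each bar; red marks lists past an adjusted p of 0.05, and the dashed line is the share over all protein-coding genes. Ribosomal protein genes lie above the line at 31.2% and chemoreceptor and cuticle protein genes below it, the last of these with no bar.

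The sequence at summits was AT-rich and carried a family of related short words. GC content was 34.0% in the 25 bp bin just downstream of the summit and 44.8% at the outer edge of the 400 bp examined. Among 2080 words of 6 bases, 362 passed the test, 189 more frequent and 173 less frequent in peaks than in matched controls. ACAGTG occurred in 21.3% of peak windows against 7.57% of controls (odds ratio 3.30, 95% interval 2.91 to 3.73, Fisher's exact adjusted p = 1.9e-64), and GTGCAC in 10.4% against 3.38% (odds ratio 3.34, adjusted p = 4.1e-34). The words CAGTGC, CACTGA, CAGTGG, ACACTG and AGTGTA followed with odds ratios from 2.58 down to 2.40, then CTACAC (2.38), CAGGGG (2.30) and ACTGTG (2.22). Most of these words overlap one another in sequence, so they are not independent results. The words with the lowest odds ratios were TCCGGA (0.466) and GAAGGA (0.543), followed by AAGGAC, GACTCC, GTCGGA, ATCCGG, AGGACA, CAGGAC, ATCCGA and GCAGGA, which ran from 0.564 to 0.604. CAGGGG lost its call against windows beside the peaks, and AAGGAC, GACTCC, ATCCGG, AGGACA, CAGGAC and GCAGGA lost theirs in at least 1 other peak list. Copies of ACAGTG were not centred on the summit: their density was 2.16 per kb and peak at -88 bp on the reference strand and 1.97 at 87 bp, against 0.433 at 12 bp.

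**Figure D5:**
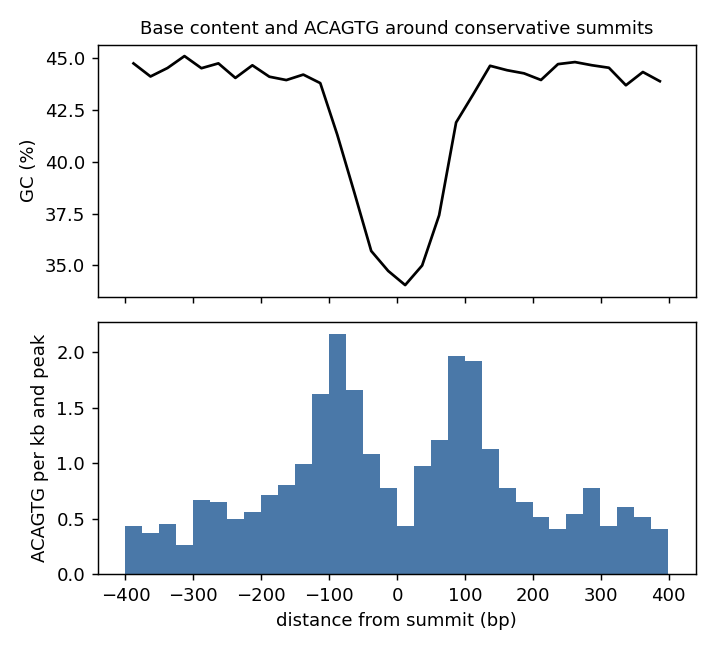
GC content (upper y axis, %) and density of ACAGTG on either strand (lower y axis, copies per kb and peak) in bins of 25 bp around the 1849 conservative summits (x axis, bp). The word is most frequent at -88 bp and 87 bp, where GC content is between that of the centre and that of the flanks.

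Of the 28 consensus motifs, 2 passed and 5 did without adjustment. The CTCF motif was found in 30 peaks, 1.62% against 0.324% of controls (odds ratio 5.11, 95% interval 3.30 to 7.91, Fisher's exact adjusted p = 3.82e-09), and passed in each replicate's own list with odds ratios of 7.04, 8.23 and 5.17. The call was lost with the 522 peaks shared by all replicates (odds ratio 4.81, Fisher's exact adjusted p = 0.16). GAGA repeats were found in 3.24% against 2.08% (odds ratio 1.59, Fisher's exact adjusted p = 0.0273), with odds ratios of 1.96, 1.52 and 2.84 in the replicates, of which replicate 2 did not pass. The GAGA call was lost in a 100 bp window (odds ratio 0.99), against windows beside the peaks (0.832), with overlapping peaks merged (1.5) and with an IDR of up to 0.05 (1.30). The odds ratio was higher in 400 bp windows (2.17, Fisher's exact adjusted p = 3.55e-17) and among the 522 shared peaks (3.11, Fisher's exact adjusted p = 5.97e-05), where no other motif passed. The Initiator and Mef2 motifs had a Fisher's exact adjusted p = 0.0692 each. In the lists of replicates 1 and 3 both passed, Initiator as less frequent (odds ratios 0.792 and 0.773) and Mef2 as more frequent (1.33 and 1.39), and the CAGCTG E-box passed in replicate 1 (1.36). Apart from CTCF and GAGA, none of the motifs passed in the main comparison, Zelda, DRE and Motif 1 among them. Mef2 passed as more frequent in 400 bp windows (1.42), beside the peaks (1.92), in the largest list (1.26), with the highest score (1.31), with an IDR of up to 0.05 (1.23) and without repeat-masked windows (1.26). Windows beside the peaks were matched neither on GC nor on TSS distance class. Against these windows, CTCF (odds ratio 5.89), DRE (5.32), TATA box (1.87), Tinman (1.40), homeodomain (1.40) and GATA motifs (1.21) also passed as more frequent. CA repeats (0.681), Pho (0.615) and nuclear receptor monomer motifs (0.35) passed there as less frequent. In 400 bp windows, DRE (1.55), Motif 1 (1.68), CA repeats (1.43) and the CAGCTG E-box (1.43) passed as more frequent, and Initiator (0.855), Pho (0.801) and Bicoid (0.783) as less frequent. In 100 bp windows CA repeats passed as less frequent (0.417). Initiator (0.863), Bicoid (0.753) and the CATATG E-box (1.25) passed in the largest list, and the nuclear receptor monomer (0.181) with the highest score.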

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

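The tests on peaks outside the 6 arms and on chromosome 4 were chosen after the results were seen. The conservative list held 85 peaks outside the 6 arms, which no comparison used, 83 on unplaced sequences of X and 2 on Y, replicate 1 held 42 and replicate 2 held 81, while replicate 3 held 0 of 903, which allows a share of up to 0.332% by the limit of 3 counts. The smaller number of peaks in replicate 3 does not account for this, since the 903 strongest peaks of replicates 1 and 2 held 24 and 41 outside the arms. The candidate lists before thresholding showed the same contrast, with a share of 0.465% in replicate 3, 2.46% in replicate 1 and 2.62% in replicate 2 (ratio to both together 0.183). The difference was therefore present before the threshold, consistent with a difference in reads or their filtering on these sequences. No biological explanation was tested, because the labels name no difference between the replicates.

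The conservative list held 0 peaks on chromosome 4. Chance on a short chromosome is argued against by the candidate list, whose 137496 peaks outside the conservative list held 43 on 4 where length gives 1385 (ratio 0.0311, exact 95% interval 0.0225 to 0.0418). The candidate share leaves 0.571 thresholded peaks expected on 4, too few for 0 to differ (exact binomial p = 1), so the test adds nothing to the candidate count itself. Candidate lists of replicates 1 and 2 held 50 and 45 peaks on 4, and that of replicate 3 held 745 against 1250 by length. The candidate list of the conservative peaks, with 43, was thus close to replicates 1 and 2 and far from replicate 3. The scarcity may therefore lie in the reads, the control or the normalization before thresholding, which cannot be separated with peak lists, and a biological absence from chromosome 4 was not tested.

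Promoter peaks may arise from sites prone to recovery in ChIP. Without peaks within 500 bp of tRNA genes or 1000 bp of ribosomal protein gene TSSs, 1802 of 1849 peaks were left, and 41.5% of their summits were at promoters. Most promoter summits thus lay away from those genes. Too few peaks were removed for the share to fall to the highest of the random placements (14.0%), so that comparison decides nothing. Among candidate peaks with an IDR above 0.05 the promoter share was 10.2%, so promoters were not over-represented among candidates that repeat poorly. With an IDR of up to 0.05 the share was 30.1%. Sites recovered repeatedly in ChIP would have a low IDR and fall outside the first set, so its share does not weigh on them. Sites open in chromatin in general and biological explanations were not tested, since no peaks of another protein were analysed here.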

How the results depend on the processing

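Tests with the highest score only, an IDR of up to 0.05, merged peaks, tRNA-adjacent peaks or repeat-masked windows left out were chosen after seeing the data. Of 694 values under alternatives, 578 for single lists, arms, motifs or words kept their side of the threshold. These include items without a call in either setting, and direction was compared only where either setting gave a call. For summaries, 38 values kept their side of the threshold, moved within their spread or, as counts of calls, stayed within a fixed fold of the main count. Of the single items, 27 gained a call, 15 lost one and 16 turned direction, while 20 summaries moved. An IDR under 0.01 removed no peak, so its 87 values were not counted. The promoter share stayed above random placements in every alternative, from 30.1% (IDR up to 0.05, and a 200 bp window on the main list) to 53.3% (peaks shared by all replicates). The share of peaks in all replicates (28.2%) was 16.4% in the largest list and 20.6% with a reciprocal overlap of at least 50%. It was 31.1% without replicate 1, 29.9% without replicate 2 and 48.7% without replicate 3. Leaving out 1 replicate gave a rho of 0.657 to 0.768 and a mean promoter share of 47.7 to 48.4%; pooled lists could not be made without a replicate. The cause was not tested for the changes that follow. With the largest list, mean rho was 0.543. The arms past the threshold (1) became 3 by TSS number, 4 with the largest list, 0 with peaks shared by all replicates, 0 in the list of replicate 3, 2 with the highest score and 4 with IDR up to 0.05. X turned to depletion at 15.8% (largest list) and 15.6% (IDR up to 0.05), 3L to excess at 22.7% (largest list) and 3R at 26.2% (IDR up to 0.05). Gene lists past the threshold (3) became 6 by gene body, a rule that was not matched on gene length. There dorsoventral (ratio 3.73), BTB-domain (4.80) and ecdysone pathway genes (6.73) turned to excess, as did trachea and epidermis genes with IDR up to 0.05 (5.15). Motifs past the threshold (2) became 10 in 400 bp windows, 10 against windows beside the peaks, 6 with the largest list, 1 with peaks shared by all replicates, 4 with the highest score and 1 with merged peaks. Odds ratios that crossed 1 with a call in either setting were GAGA (0.99) and CA repeat (0.417) at 100 bp, Motif 1 (1.68) at 400 bp, and, beside the peaks, GAGA (0.832), CA repeat (0.681), TATA box (1.87), homeodomain (1.40) and GATA (1.21). Words of 6 bases past the threshold (362) became 1121 against windows beside the peaks, which are matched neither on GC nor on TSS distance class. CTCF lost its call among the 522 shared peaks (odds ratio 4.81, Fisher's exact adjusted p = 0.16).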

Other observations

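The tests of divergent genes and of GC content were chosen after the results were seen, as were the check on peaks apart from explored ones, the repeated word scan and the comparison of pairs with other words. Promoter summits lay between TSSs of genes transcribed away from each other, any protein-coding TSS within 1000 bp counting, in 328 of 791 cases (41.5%). The same offsets from randomly drawn TSSs over 2 kb from a conservative summit gave 22.5% of 7910 (odds ratio 2.43, 95% interval 2.09 to 2.83, Fisher's exact test, two-sided, p = 3.24e-29). Of the 25 genes with the strongest peaks within 1000 bp of a TSS, 12 had the summit between divergent TSSs, among them Ugalt with eIF2Bbeta, mRpL41 with CG8079, Tcs5 with CHMP2B, Art3 with mRpS10 and CenG1A with mRpS23, whose summits were intergenic. A candidate explanation is that the protein favours promoters shared by divergent genes, but the drawn TSSs were not matched on expression or on the chance of a peak. The 100 bp around promoter summits had a GC content of 33.0 ± 10.3% (SD over 791 summits), against 40.2 ± 10.9% at the drawn positions (permutation p = 2e-05, two-sided, the smallest that 100000 resamples can give).

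ACAGTG lay beside the summit more than at it. The word had the smallest p in the scan of all peaks, which held the peaks tested here too. Its position was explored on every other peak along the arms, and the tests were run on the 924 peaks left. A scan of the 925 explored peaks alone also ranked it 1 of 2080 by p (odds ratio 3.27, Fisher's exact p = 3.53e-34), so the same choice follows without the tested peaks. Its density in the 3 bins of 25 bp that begin 50 bp from the summit was 3.52 times that at 200 to 400 bp, higher than in 100% of the other words of the same bases (median 0.927, highest 2.92). Its density under 50 bp over that in these bins was 0.393, below 99.4% of the words (median 0.828). Copies on the left and right, within 5 bins of the summit, occurred together in 50 peaks (odds ratio 3.80, Fisher's exact p = 5.2e-10). That ratio exceeded 88.3% of the words (median 1.81), and 684 peaks held no copy, so it does not separate pairing from a word confined to some of the peaks. Of the 55 peaks with 2 copies, 44 had them on opposite sides (exact binomial p = 8.7e-06 against equal chances), which other words were not compared for.

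Neighbouring peaks can overlap, so 171 of the 924 peaks had an explored peak within 1000 bp. In the 753 others the ratio was 3.71, higher than in 100% of the words, the central ratio was 0.375, below 99.4% of them, and the pair odds ratio was 3.89, above 86.6% of the words. Of the 43 peaks with 2 copies there, 35 had them on opposite sides (exact binomial p = 4.19e-05 against equal chances), without a comparison to other words. Pairing thus remains open. The stronger of the 924 peaks, by the middle rank of signal, held the word in 30.5% and the weaker in 21.6% (odds ratio 1.59, Fisher's exact p = 0.00268). In the 753 peaks this relation did not pass (28.5% against 22.5%, odds ratio 1.36, Fisher's exact p = 0.0662), so it remains open. A summit placed midway between neighbouring bound sites, or an AT-rich stretch between them that the protein needs, could each give the flanking arrangement, and peak positions do not separate these. The words of 7 bases with the highest odds ratios were ACAGTGG (6.13), CAGTGTA (5.39), CACAGTG (4.98) and CACTGAG (4.81).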
